A study of Mus musculus with 2 samples.

How the data were processed

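Chromatin immunoprecipitation with sequencing (ChIP-seq) against MAFK was measured in the mouse embryonic stem cell line ES-E14, which the labels call male. The labels name 2 biological replicates of 1 group and give both the same source of cells, so the spread between them can be partly technical. No second condition was given, and the control experiment that the labels point to was not analysed here. The read depth of each replicate is unknown, because the files hold regions and not reads.

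The deposited files are lists of regions on mm10. The aligner, the peak caller and the read filters are not given in the sources used here. Per the text notes deposited with the samples, the lists come from 2 processing runs. In the first run, relaxed lists of regions with background were made for each replicate and for the pooled replicates, and an optimal and a conservative list were derived from these 3 with the irreproducible discovery rate (IDR). In the second run, lists were derived from other alignments for each replicate and for both together. The optimal list of the first run is the main list, and the replicates' own thresholded lists are from the second run, so a comparison between them crosses both runs.

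The signal value of each region is a score that the authors deposited without stating its scale, and it was used only to describe and rank regions. The replicates' signal values come from lists processed separately, so they were compared by rank, and a Pearson correlation of log2 signal was added for description. The deposited significance column holds a −log10 q-value, as the region format defines it, and the deposited p-value column holds no values. The deposited IDR score of a thresholded list is a scaled value, and 16818 of the 16865 regions of the optimal list were at or above the score of an IDR of 0.05. The remaining regions lay just under it, with 537 as the lowest score. Summits were taken from the deposited summit offset. Coordinates are printed 1-based.

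Sequences came from the GRCm38 reference, which is the assembly of mm10, and genes from GENCODE vM21. No region of the lists used lay beyond the end of its chromosome. Analyses of sequence and location used the 16836 optimal regions on the assembled chromosomes. The 19 mitochondrial regions and the 10 on unplaced sequences were left out of these and kept in the overlaps between lists. No region of the optimal list was on Y.

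The tests of this paragraph were fixed before the data were examined. Overlap meant at least 1 bp shared, and the overlap of the replicates was set against 100 random placements. The rank correlation of signal had a permutation test with 100000 permutations. Location of each summit was compared with 10 random positions per peak outside assembly gaps, in the order within 1 kb of a transcription start site (TSS), exon, intron and intergenic. Sequence elements were searched on both strands within 50 bp of the summit and, as background, in windows of the same width centred 1000 bp to either side. The 16 element families included a reversed and a shuffled control sequence. Of these, the T-MARE and C-MARE palindromes and the SOX-OCT element were allowed 2 mismatches, the NRF1 element 1 mismatch and the others none. The 32887 of 32896 sequences of 8 bp that occurred were tested in the same windows at an adjusted p under 0.01. Gene lists were compared with the other protein-coding genes for a summit within 10 kb of any TSS of the gene. X density used the length outside assembly gaps and an exact binomial test. Other comparisons of shares used Fisher's exact test, two-sided. Adjusted p-values are Benjamini-Hochberg values over the families or lists tested together, and p-values below 1e-300 are given as that floor. Intervals of shares are 95% Wilson intervals, and those of odds ratios are 95% intervals on the log scale. All of them cover counting error only. Regions are not independent replicates, and a p-value over regions describes these lists.

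Other values were chosen after the data had been seen. These are the comparison of gene lists with the housekeeping list, the share with any of 3 element forms, the distance of the element from the summit and the groups of 10% by signal. They are also the regions not shared by the replicates, the overlap of the optimal with the conservative list, the weak regions and the counts that describe the regions of each gene list. The gene-list test does not account for the number of TSSs of a gene or its expression, and a nearby region does not show that the gene is a target.

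The 9 gene lists and the naming rule were set in advance too. Hmox1 is in 2 lists. The text names regions from the 20 of highest signal among those that overlap both replicates' lists, with the nearest protein-coding TSS. It also names up to 4 members of each gene list with the highest signal within 10 kb, all small MAF and CNC factor genes, and the 10 sequences of 8 bp with the smallest p. Ties at the floor were ordered by fold.

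Alternatives covered the peak list, each replicate's own list, the overlap rule, the TSS and gene distance, the window, the background, the element mismatch, ranking by q-value, non-repeat length for X and random gene lists matched on promoter CpG. The statistics were tested on simulated data. With 20% of 4000 windows given the composite element, 20.1% were found to hold it against 0.10% of background windows. In lists of 20 genes with a chance of 65% for a nearby region, 94.6% of 1000 lists had an unadjusted Fisher's exact p under 0.05. The share was 3.0% of lists drawn at the genome level. Adjustment over lists and other list sizes were not simulated. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Signal tracks that the notes mention were not used here.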

Results

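MAFK is a small MAF transcription factor that binds DNA as a homodimer or together with a CNC factor such as NRF2, NFE2 or BACH1. Its binding was mapped by ChIP-seq in ES-E14 mouse embryonic stem cells, in 2 biological replicates. The optimal list of the authors held 16865 regions with a median signal value of 27.9. The thresholded lists of replicates 1 and 2 held 7748 and 9541 regions. With 1 condition, the comparisons open to the data are between the replicates, between binding sites and background sequence, and between classes of sites and genes.

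The regions of highest signal lay mostly inside or between genes and away from promoters. The first was in an intron of Esrrb, an orphan nuclear receptor gene of the pluripotency network, at chromosome 12, 86488041 to 86488429. It had a signal value of 509.4 in the pooled list and of 266.6 and 247.5 in the relaxed lists of replicates 1 and 2, and its summit was in repeat-masked sequence. The next were in introns of Aff3 at chromosome 1, 38549276 to 38549662 (signal 470.3), of Ppip5k2 near Gin1 at chromosome 1, 97768109 to 97768476 (465.9), and of Kazn at chromosome 4, 142171471 to 142171813 (459.5). A region at the promoter of Snrpc, a U1 snRNP component, had its summit 162 bp from the TSS on chromosome 17, 27839639 to 27840087 (453.7). Others of the first 20 were nearest to Sulf1, Col13a1, Gatad2a, Fam3c, Plekha3, Efcab2, Rps15a, Sos1, Rhoh, Casr, Epha2, 1810013L24Rik, Dym and Atxn1, with signal values from 395.6 to 438.9. Of these 20 regions, 14 were intronic, 5 intergenic and 1 in a UTR, 2 were within 1 kb of a protein-coding TSS, and 6 were more than 50 kb from one. All 20 held the antioxidant response element core, and 16 held the composite element described next.

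MAFK summits were marked by the sequences that small MAF factors are known to bind. The NFE2-type composite element TGASTCAGCA, which joins a CNC site to a MAF site, lay within 50 bp of 28.2% of summits (4754 of 16836, interval 27.6 to 28.9) and in 0.0891% of flanking windows. The MAF core TGCTGA was at 62.8% of summits against 7.29% of flanks, the antioxidant response element core TGASNNNGC at 60.3% against 7.15%, and the T-MARE palindrome at 39.2% against 0.401%. Every composite element also holds the MAF core and the antioxidant response element core, so these shares overlap. At least 1 of the composite element, the palindrome and the antioxidant response element core was present at 64.3% of summits and 7.32% of flanks. The AP-1 element TGASTCA, which is contained in the composite element, was at 37.8% against 1.81%, and the AT-rich extended MAF core at 28.4% against 1.10%. Fisher's exact test gave an odds ratio of 441 for the composite element (308 to 632), with p at the floor of 1e-300. With 1 mismatch allowed the share was 53.1% against 1.72% of flanks. In the replicates' own lists the composite share was 37.5% and 34.3% (35.9% ± 2.32, SD, n = 2), so the shift from the flanks was far larger than the spread between replicates.

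The other families were found at fewer summits. The C-MARE palindrome, also a MAF element, was at 1.62% of summits against 0.0267% of flanks (odds ratio 61.7, exact test, adjusted p = 2.20e-116), with an odds ratio of 99.2 in the list of replicate 1 and 107.1 in that of replicate 2. The CTCF core was at 2.10% of summits against 0.505% of flanks (odds ratio 4.22, exact test, adjusted p = 2.39e-57). The CREB-type element was at 0.279% against 0.0594% (exact test, adjusted p = 1.37e-09). SOX-OCT composite sites were at 0.665% against 0.232% (exact test, adjusted p = 1.09e-12) and ESRRB-type sites at 0.398% against 0.273% (adjusted p = 0.0241). The NRF1 element (0.362% against 0.148%), the GC box (0.968% against 0.573%) and the ETS element (0.291% against 0.104%) also passed, with adjusted p-values of 4.82e-06, 1.56e-06 and 4.82e-06. ESRRB-type sites did not pass in the list of replicate 1 (exact test, adjusted p = 0.113) or replicate 2 (odds ratio 1.11, adjusted p = 0.717), and the ETS element did not pass in that of replicate 1 (0.219% against 0.136%, odds ratio 1.62, adjusted p = 0.191). The NRF1 odds ratio was 2.45 in the optimal list and 4.80 in the list of replicate 2. The reversed control was at 0 summits and in 1 flanking window. The shuffled control GTTCAG was at 5.67% of summits against 5.09% of flanks (odds ratio 1.12, exact test, adjusted p = 0.0074), so a small difference of this size was also seen for a control sequence. In replicate 1's list the control had an odds ratio of 0.97 and did not pass.

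**Figure D1:**
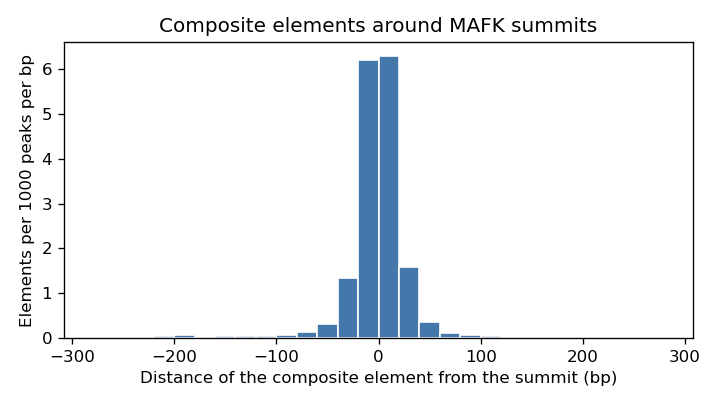
Composite elements per 1000 peaks per bp (vertical axis) in bins of 20 bp by their distance from the summit in bp (horizontal axis), for the optimal list. Elements concentrate at the summit: among 5047 peaks with an element within 300 bp, the median distance was 11 bp.

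The element sat at the summit itself. Among 5047 peaks with a composite element within 300 bp, 83.8% had the nearest within 25 bp, at a median distance of 11 bp. Without any element chosen in advance, the 10 sequences of 8 bp with the smallest p were GACTCAGC, GAGTCAGC, CTGAGTCA, ACTCAGCA, AGTCAGCA, ATGACTCA, CTGACTCA, GAGTCATC, GTCAGCAA and GTCAGCAC. GACTCAGC was at 27.8% of summits against 0.413% of flanks, and GTCAGCAC, the last of these, at 5.65% against 0.258%. In all, 1716 sequences of 8 bp were enriched and 1480 depleted. Of the enriched, 47 held the MAF core TGCTGA and 157 (9.15%) held TGCTG or an AP-1 element. These counts leave out pieces of the composite element that hold neither, such as GACTCAGC and GAGTCAGC. The enriched and depleted counts were 1020 and 684 in the strongest 50% of regions, 872 and 474 in the list of replicate 1, 1212 and 974 in that of replicate 2, and 743 and 427 among regions that overlap both replicates' lists.

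The composite element was more frequent at stronger sites. It was at 44.1% of the strongest 25% of regions by signal and at 13.7% of the weakest 25% (odds ratio 4.95, 4.45 to 5.51, Fisher's exact p = 1.11e-214). The odds ratio was 2.99 in replicate 1's list, 2.50 in the strongest 50% of regions and 2.47 among regions that overlap both replicates' lists, all past the threshold. From the weakest to the strongest 10% of regions its share went from 7.90% to 52.9%. Regions within 1 kb of a TSS were 590 of 4209 in the strongest and 831 of 4209 (19.7%) in the weakest 25% (odds ratio 0.66, exact p = 2.61e-12). Of the weakest 10% of regions, 24.1% were near a TSS. This difference did not pass in replicate 1's list (0.94, exact p = 0.515) or replicate 2's list (0.92, p = 0.267). In the strongest 50% of regions it turned to an odds ratio of 1.05 (exact p = 0.625), and among regions that overlap both replicates' lists to 1.03 (p = 0.835).

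**Figure D2:**
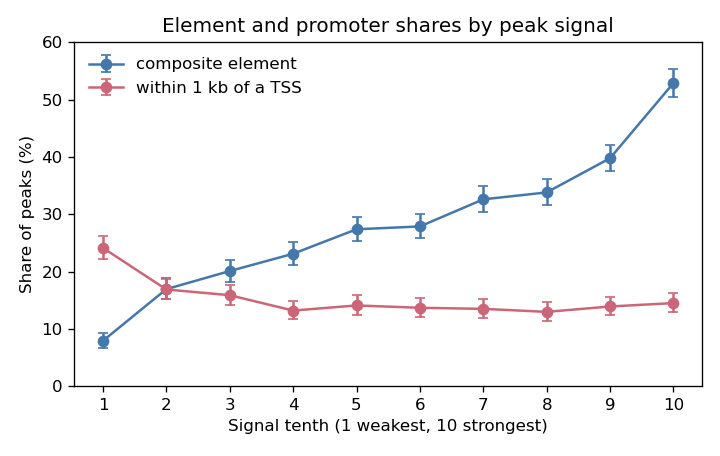
Share of optimal regions in percent (vertical axis) that hold the composite element or lie within 1 kb of a TSS, by signal from the weakest (1) to the strongest (10) 10% of regions (horizontal axis), with 95% Wilson intervals as bars. The composite share goes from 7.90% to 52.9%, and the promoter share is 24.1% in the weakest group and 14.5% in the strongest.

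Of the 9 gene lists, that of the antioxidant response was the one most often found near MAFK regions. Of the 28 genes of the antioxidant and NRF2-type cytoprotective list, 24 had a summit within 10 kb of a TSS, against 26.8% of other protein-coding genes (odds ratio 16.4, 5.69 to 47.3, exact test, adjusted p = 1.09e-09). The strongest were at Hmox1, the heme-degrading heme oxygenase 1 (signal 390.4, chromosome 8, 75083784 to 75084152, intergenic, 9638 bp upstream of the TSS), and Gsta4, a glutathione transferase (348.3, chromosome 9, 78191690 to 78192002, 94 bp from the TSS). They were followed by Txnrd1, a thioredoxin reductase (330.1, chromosome 10, 82858969 to 82859278, 66 bp from the TSS), and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis (301.3, chromosome 9, 77750574 to 77750882, 3795 bp upstream). Of the strongest regions of these 24 genes, 20 overlapped both replicates' lists, 20 held the antioxidant response element core, 9 held the composite element and 12 were within 1 kb of a TSS. The odds ratio was 37.6 with the conservative list and 26.1 with the strongest 50% of regions. Set directly against the housekeeping list, in which 5 of 15 genes had a summit, the antioxidant list differed (odds ratio 12.0, 2.66 to 54.2, exact test, adjusted p = 0.0108 over 8 lists), and the other 7 lists did not.

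Heme and iron genes and proteasome genes were also near regions more often than other genes. In the heme and iron list, 15 of 20 genes had a summit within 10 kb (odds ratio 8.18, exact test, adjusted p = 3.78e-05). These included Hmox1, which is on both lists, the ferritin chains Fth1 (signal 259.2, chromosome 19, 9978457 to 9978778) and Ftl1 (226.0, chromosome 7, 45460854 to 45461126), and the heme transporter Slc48a1 (181.7). Of the 31 proteasome subunit genes, 20 had a summit (odds ratio 4.96, exact test, adjusted p = 3.78e-05), led by Psma3 (107.0), Psmc5 (90.2), Psmb3 (83.9) and Psmc2 (67.1). Their signal was lower, with a median of 36.3 over the 20 genes against 133.1 over the 24 antioxidant genes. Of the 20 strongest proteasome regions, 13 were within 1 kb of a TSS, 12 held the antioxidant response element core, 2 held the composite element and 8 overlapped both replicates' lists. The heme and iron odds ratio was 5.17 in replicate 1's list and 13.1 within 50 kb. The proteasome odds ratio was 2.76 among regions that overlap both replicates' lists and 10.3 within 2 kb, and all of these passed.

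Regions lay at some genes of the small MAF and CNC factor list, which holds relatives and partners of MAFK and also Keap1. A summit was within 10 kb at 6 of the 10 genes (odds ratio 4.09, exact test, adjusted p = 0.0504), which did not pass. It passed in 7 of 9 alternatives, with adjusted p from 0.00756 to 0.278 over all 9. It did not pass against random lists matched on promoter CpG (permutation test, adjusted p = 0.240) or within 50 kb (exact test, adjusted p = 0.278). Mafg, another small MAF gene, had a summit 54 bp from a TSS with the composite element (signal 221.8, chromosome 11, 120630083 to 120630346). Keap1, the gene of the NRF2 inhibitor, had 3 summits within 10 kb, the strongest 46 bp from a TSS (150.7, chromosome 9, 21238739 to 21238955). Bach1, a heme-sensing repressor gene, had 1 in an intron at 1122 bp (145.3, chromosome 16, 87700011 to 87700202). Weaker summits were at Maff (40.7), Bach2 (30.8) and Nfe2l2, which encodes NRF2 (22.4), and the Bach2 region overlapped neither replicate's list. The nearest summits to Nfe2, Nfe2l1, Mafk and Nfe2l3 were 11369, 42297, 96409 and 111688 bp away.

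Pluripotency genes had nearby regions in the optimal list, but the call did not hold in all alternatives. Of 20 genes, 13 had a summit within 10 kb (odds ratio 5.06, exact test, adjusted p = 0.000895), led by Tfcp2l1, a factor of naive pluripotency (signal 252.9, chromosome 1, 118621117 to 118621390). Next came Fgf4 (133.2), an intronic region of Esrrb at 3474 bp from a TSS (87.8) and Tdgf1, a NODAL co-receptor gene (51.8). Of these 13 strongest regions, 4 overlapped both replicates' lists, as did 35.4% of all optimal regions. The call did not hold in replicate 1's list (odds ratio 2.70, exact test, adjusted p = 0.0829) or among regions that overlap both replicates' lists (1.98, adjusted p = 0.349). It held in replicate 2's list (odds ratio 3.90, exact test, adjusted p = 0.00846). Over the 9 alternatives the adjusted p went from 0.00278 to 0.349.

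The lists of other lineages and the housekeeping list did not pass. Mesendoderm genes had summits at 4 of 15 genes, Gsc (signal 53.2), Eomes (33.8), Nodal (20.2) and Gata4 (19.3), with an odds ratio of 0.99 and an adjusted exact p = 1. Neuroectoderm genes had them at 5 of 12 (odds ratio 1.95, adjusted exact p = 0.487), among them Neurog1 (56.7), Zic1 (33.1) and Nes (16.7), and none of the strongest regions of the 5 genes overlapped both replicates' lists. Erythroid and globin genes had them at 5 of 15 (odds ratio 1.36, adjusted exact p = 0.636). The region of the embryonic globin gene Hbb-y had a signal of 201.4 (chromosome 7, 103860950 to 103861214), that of Slc4a1 49.0, and Hba-a1 and Hba-x shared 1 region of 37.0. Housekeeping genes had the same count and odds ratio, among them Gapdh (100.3), Actb (27.3) and Polr2a (22.6). Over the alternatives the odds ratio went from 0.526 to 1.73 for mesendoderm, 0.317 to 2.06 for neuroectoderm, 0.526 to 2.89 for erythroid and 0.867 to 2.75 for housekeeping genes, and none passed. For erythroid genes it was 2.29 in replicate 1's list and 2.89 among regions that overlap both replicates' lists.

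**Figure D3:**
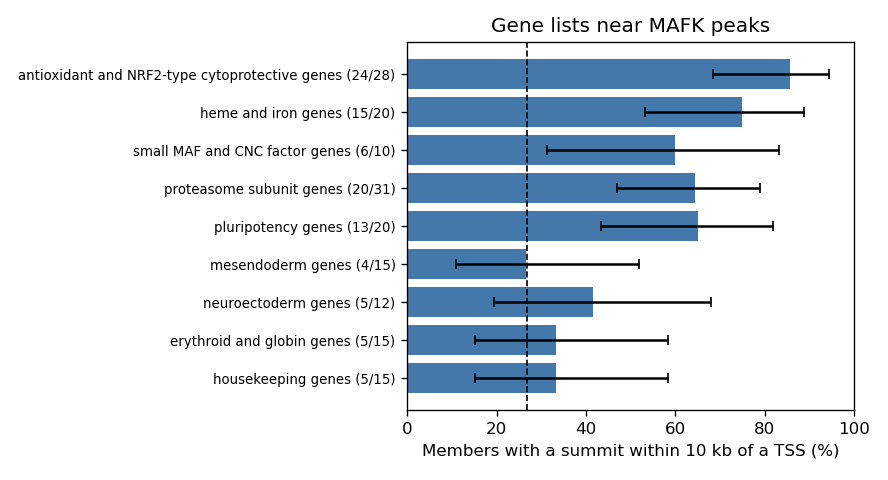
Share of the members of each gene list with a summit within 10 kb of a TSS (horizontal axis, percent), with 95% Wilson intervals as bars, counts beside the names and other protein-coding genes as a dashed line near 26.8%. The antioxidant list stands at 85.7% and the mesendoderm list at 26.7%.

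MAFK regions were enriched at promoters, although most lay elsewhere. Of the summits, 15.3% were within 1 kb of a TSS against 6.24% of random positions (odds ratio 2.70, 2.58 to 2.83, p at the floor). Intergenic summits were fewer than random positions (39.4% against 49.9%, odds ratio 0.65, exact test, adjusted p = 1.23e-147), and intronic ones slightly more frequent (41.6% against 40.4%, adjusted p = 0.0029). Exonic summits did not differ from random positions in the optimal list (3.71% against 3.52%, exact test, adjusted p = 0.197) but did in the list of replicate 2 (4.01% against 3.37%, adjusted p = 0.0017). In the replicates' lists the promoter share was 13.3% and 15.1% (14.2% ± 1.25, SD, n = 2). The median distance to a protein-coding TSS was 17144.5 bp, and 28.8% of summits were beyond 50 kb.

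**Figure D4:**
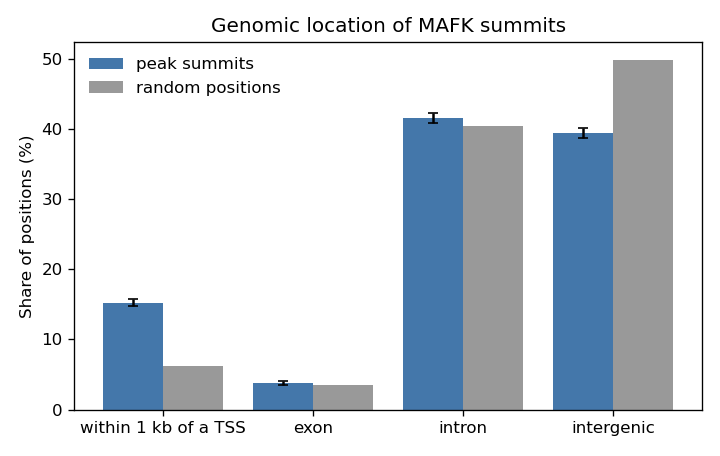
Share in percent (vertical axis) of optimal summits and of random positions in each location class (horizontal axis), with 95% Wilson intervals as bars on the summits. Summits within 1 kb of a TSS were 15.3% against 6.24% of random positions, and intergenic summits 39.4% against 49.9%.

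Promoter and distal regions differed in their elements. The comparison had no background of unbound promoters. It cannot tell whether a difference belongs to the bound regions or to promoter sequence in general. The composite element was at 17.2% of the 2569 promoter regions and 30.2% of the 14267 distal ones (odds ratio 0.48, 0.43 to 0.53, exact test, adjusted p = 3.73e-44). The MAF core was at 44.6% against 66.1%, and the T-MARE palindrome at 24.7% against 41.8%. ETS elements were more frequent at promoter regions (1.40% against 0.0911%, odds ratio 15.6, exact test, adjusted p = 2.19e-19), as were GC boxes (3.46% against 0.519%), NRF1 elements (1.32% against 0.189%) and CREB-type elements (0.623% against 0.217%). In the optimal list SOX-OCT composite sites were less frequent there (0.272% against 0.736%, odds ratio 0.37, exact test, adjusted p = 0.0077). This call did not hold in the list of replicate 1 (odds ratio 0.59, exact test, adjusted p = 0.418) or replicate 2 (0.49, adjusted p = 0.204), in the strongest 50% of regions, among regions that overlap both replicates' lists or with promoters taken as within 5 kb, with adjusted p from 0.00657 to 0.418 over the 7 alternatives. The CREB-type call did not hold in the list of replicate 2 (exact test, adjusted p = 0.0622) or in the last 3 of these settings, with adjusted p from 0.00132 to 0.234 over the 7 alternatives. The NRF1 odds ratio was 7.07 in the optimal list, 3.25 in the list of replicate 2 and 2.81 with promoters within 5 kb, and it passed in each. The CTCF core did not pass in the optimal list but was less frequent at promoter regions in the lists of replicate 1 (odds ratio 0.38, exact test, adjusted p = 0.011) and replicate 2 (0.46, adjusted p = 0.0028). Its odds ratio turned to 1.08 with promoters within 5 kb (exact test, adjusted p = 0.576), and over the 7 alternatives its adjusted p went from 0.00283 to 0.576. In all, 12 of the 16 families passed, including the shuffled control, which was at 4.67% against 5.85% (exact test, adjusted p = 0.024) and did not pass in either replicate's list. With promoters taken as within 5 kb of a TSS, the odds ratio was 0.72 for the composite element, 7.58 for ETS elements and 3.19 for GC boxes, all past the threshold.

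Regions were sparse on the X chromosome. The 258 X regions gave a density of 0.228 of that on the autosomes (0.201 to 0.258, exact binomial p = 5.28e-206). The labels call the line male, which would give 1 copy of X, but copy number was not measured. In the lists of replicates 1 and 2 the ratio was 0.244 and 0.188 (0.216 ± 0.040, SD, n = 2). Summits were in repeat-masked sequence less often than their flanks, at 16.4% against 26.5% (odds ratio 0.54, 0.52 to 0.57, exact p = 6.26e-150).

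The replicates found many of the same sites and ranked them alike. Of the 7748 regions of replicate 1, 6034 (77.9%, 76.9 to 78.8) overlapped a region of replicate 2, where random placement gave 16.1 ± 4.18 (SD over 100 placements, at most 29). Of the 9541 regions of replicate 2, 63.0% overlapped replicate 1. Unshared regions had lower signal than shared ones, with a median of 17.4 against 31.4 in replicate 1 and of 16.2 against 31.8 in replicate 2. Of the unshared regions of replicates 1 and 2, 94.9% and 94.3% overlapped the relaxed list of the other replicate. Those relaxed lists are from the first run, include background and hold 300000 and 264306 regions. No random placement was made for this overlap. Across 5968 shared regions, signal had a Spearman correlation of 0.79 (permutation p = 1e-05, the smallest that the permutations can give), and log2 signal a Pearson correlation of 0.84. These are correlations across regions, which are not independent replicates.

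**Figure D5:**
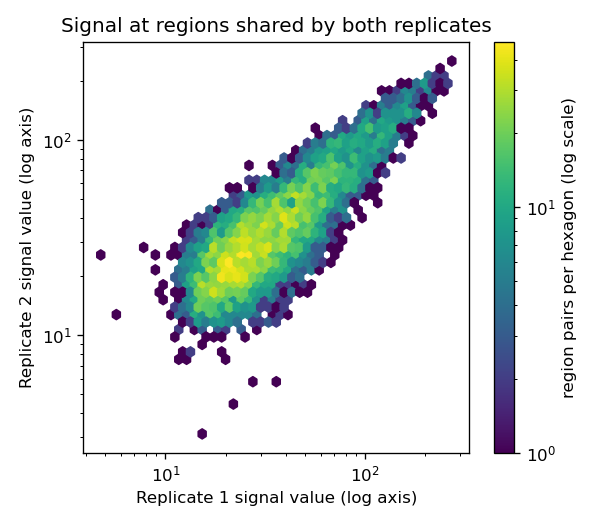
Signal value of replicate 1 (horizontal log axis) against replicate 2 (vertical log axis) at 5968 regions shared by their thresholded lists, with colour for the number of region pairs per hexagon on a log scale. Signal rises together, with a Spearman correlation of 0.79 across regions.

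The optimal list held many regions that were not in the replicates' own thresholded lists. It is from the first run and those lists are from the second. Of the optimal regions, 83.6% overlapped the second-run list over both replicates, so part of the gap can come from the change of run. In all, 5962 optimal regions (35.4%, 34.6 to 36.1) overlapped both replicates' lists, 44.3% overlapped replicate 1's, 52.9% replicate 2's and 38.2% neither. With the full ranked lists of the replicates in place of the thresholded ones, 69.6% overlapped both and 4.60% neither, and with a reciprocal overlap of 50% the share in both was 28.1%. The optimal list also did not contain the conservative list of the same run: 85.8% of the 16082 conservative regions overlapped it. In the optimal list 413 regions (2.45%) ranked below place 33730 of the relaxed pooled list by signal, and 81.1% of those had a stronger region within 300 bp.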

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

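The rank ranges used here were chosen only after the lists had been seen. Signal was present in data outside the main measurement, in relaxed pooled regions that overlap no thresholded list. Of these 278096 regions, 1.30% (1.26 to 1.34) held the composite element within 50 bp of the summit, against 0.0891% of the windows flanking optimal summits. The share was 13.0% of the 1395 such regions among ranks 1 to 20000 of the relaxed list, 6.99% at the next ranks up to 40000, 2.34% from there to 80000, 0.904% from there to 150000 and 0.417% beyond. The optimal list also held 19 mitochondrial regions, with a median signal value of 48.3, and 10 regions on unplaced sequences. The analyses of sequence and location left these out, and the overlaps between lists included them.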

How the results depend on the processing

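The second-run list over both replicates and the regions that overlap both replicates' lists were chosen as alternatives only after the data had been seen. Of 164 alternative values for 21 results, 137 kept their direction and their side of the threshold or stayed within the spread, 7 newly passed, 4 no longer passed, 11 changed direction and 5 moved. Several results kept direction and side of the threshold in all alternatives run. The promoter share was 10.6% within 500 bp of a TSS, against 3.42% of random positions (odds ratio 3.36). Within 5 kb it was 37.1% against 23.9% (odds ratio 1.88). The composite share was 23.2% to 53.1%, with odds ratios of 2.47 to 4.94 by strength and 0.48 to 0.72 between promoter and distal regions. The X ratio was 0.188 to 0.285. The repeat-masked share and the antioxidant, heme and proteasome calls were kept too. The share in both replicates was 28.1% with a reciprocal overlap of 50% and 69.6% with the ranked lists. The odds ratio of promoter location by strength was 1.05 in the strongest 50% of regions. It was 0.92 to 0.94 in the replicates' own lists and 1.03 among regions in both lists. The replicates' own lists are from the second run and are shorter than the optimal list. They change the run and the list size along with the replicate. Enriched sequences of 8 bp numbered 1020 in the strongest 50%, 872 to 1212 in the replicates' own lists and 743 among regions in both lists. The gene-list odds ratios that crossed 1 were not past the threshold in the main list or the alternative. For neuroectoderm genes they were 0.573 to 0.953 in the replicates' own lists and 0.905 in the second-run list over both replicates. They were 0.317 among regions in both lists and 0.963 at 50 kb. For mesendoderm genes the values in the replicates' own lists were 0.97 to 1.73, of which only that of replicate 2's list crossed 1. The value among regions in both lists was 1.22. Those that crossed 1 were also 0.867 for housekeeping genes in the strongest 50% and 0.526 for erythroid genes at 2 kb. The cause was not tested. Read depth is unknown, so a site missing from a list is not shown to be unbound. No analysis paired between conditions was possible because there is 1 group. The tests of summits against flanks pooled the windows and did not use the match of each summit to its own flanks.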

Other observations

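The comparisons of how often elements were occupied, that of unoccupied elements in repeats and the tests of the repeat content of X, of stronger neighbouring regions, of the elements in weak regions and of the base before TGA were chosen only after the result was seen. How often a site in the genome sequence was bound depended on the bases around it. GRCm38 holds 22501 composite elements, and 22.1% (21.6 to 22.7) had an optimal summit within 50 bp. Of the 383 that extend to the full palindrome TGCTGASTCAGCA, 368 were occupied (96.1%, 93.6 to 97.6). With the GC of that palindrome but not its outer T the share was 54.2%, and with C next to TGA and neither of the outer bases it was 16.7%. TGACTCAGCA was occupied more often than TGAGTCAGCA (3205 of 12756 against 1401 of 9362, odds ratio 1.91, 1.78 to 2.04, palindromes left out). Copies of 1 repeat sequence were counted as separate elements, and this comparison was not made without them. It cannot tell the base from the repeat family that carries it. Elements within 1 kb of a TSS were occupied more often than others (30.9% against 21.5%, odds ratio 1.63, 1.45 to 1.83), although promoter regions held the element less often. Repeat-masked and other elements did not differ (22.2% against 22.1%, odds ratio 1.01, 0.94 to 1.08).

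A hypothesis is that a CNC partner, which prefers A or G before TGA, may set which elements are bound. Leaving out full palindromes, elements with A or G there were occupied at 22.9% and those with T at 4.12%, an odds ratio of 6.92 (5.80 to 8.26). The values differ within that class, at 27.1% for A and 14.4% for G. C had 26.0%, which includes elements with more of the palindrome, such as GC before TGA at 54.2%. With C and neither outer base of the palindrome it was 16.7% (15.4 to 18.1). This was below A but not below G alone (13.4 to 15.5 for G), and it was above T. The pooled value for A or G is thus carried by A. Against this C class, the values go with a preference for A and not with one for G. A preference for A or G does not account for that difference from T.

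A further hypothesis, that repeat families may have spread bound elements, stays open. Of 1489 occupied elements in masked sequence, 16.3% shared their 30 bp sequence with another occupied element, against 1.09% of 3485 in other sequence, an odds ratio of 17.7 (12.5 to 25.1). Unoccupied elements gave a difference in the same direction, 38.7% of 5209 against 5.16% of 12318 (odds ratio 11.6, 10.5 to 12.8). Masked sequence is repeated whether or not it is bound, so this comparison does not bear on the hypothesis.

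The X chromosome had 0.228 of the autosomal density of regions, and 3 technical explanations were weighed. Halving every autosomal signal, as 1 X copy might do if signal follows copy number, gives a ratio of 0.435 at a signal of 20, above the measured 0.227 (0.196 to 0.262), so copy number under this simple model does not account for all of it. Composite elements are rarer on X (0.753, 0.708 to 0.800), and over non-repeat length the ratio was 0.285, so neither alone accounts for it. The ratio was also low among all relaxed pooled regions, at 0.222, and X elements were occupied at 7.20% against 22.9%. Several of these acting together, or read filtering, stay open, and no biological explanation was tested. On Y, the relaxed pooled list held 0 regions, the relaxed list of replicate 2 held 2, and 0 of 59 composite elements were occupied. Why Y had so few regions in a line labelled male was not tested.

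Promoter regions held the composite element less often and were frequent among the weakest regions. A summit displaced from its element is argued against, since within 200 bp the odds ratio was 0.489 (0.440 to 0.544). General signal at promoters may contribute: promoter regions with none of the 3 element forms overlapped both replicates' lists less often than those with one (20.8% against 43.5%, odds ratio 0.341, 0.287 to 0.406). Distal regions showed the same gap (22.5% against 42.7%, odds ratio 0.389), so the test does not single out promoters. No biological explanation was tested.

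In the optimal list 413 regions ranked below place 33730 of the relaxed list. They may be edges of stronger neighbours: 81.1% had a stronger region within 300 bp, against 6.19% of relaxed regions of the same rank range outside the optimal list (odds ratio 65.1, 50.9 to 83.4). Weak sites with the element are argued against as most of these regions, since 12.6% (9.73 to 16.1) held any of the 3 element forms, against 38.4% of the rest of the weakest 10%, which had higher signal. Whether they hold the composite element more often than regions of like signal stays open: 4 of 413 did, against 81 of 4130 relaxed regions outside the optimal list, the 10 nearest in signal for each (odds ratio 0.489, 0.178 to 1.34). No biological explanation was tested.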
